A study of Homo sapiens with 5 samples.

How the data were processed

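RNA was measured by sequencing in 5 libraries of U2OS, a human osteosarcoma cell line. Per the labels, 4 libraries came from cells that carry an inducible construct fusing YFP to the oestrogen receptor hormone-binding part and E2F1, sorted by flow cytometry into YFP-negative, YFP-low, YFP-medium and YFP-high fractions. The fifth came from parental U2OS cells without the construct. Per the labels' protocols, cells were grown with 8% fetal bovine serum and received 500 ng/ml doxycycline for 48 h, followed by 90 nM 4-hydroxytamoxifen (OHT) for a further 20 h. The labels give this treatment for the parental library too. Each group has 1 library.

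The authors deposited read counts per gene name, as raw whole numbers with no normalisation. The submitters' processing notes name CASAVA 1.8.2, bcl2fastq, Trimmomatic 0.36, HISAT2 2.0.3, HTSeq 0.6.0 and the human genome build hg19, without their order or settings. The gene annotation and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited count table holds 27992 gene names, a row with no gene name, and HTSeq's 5 classes of reads given to no gene. A second deposited table gives TPM, a unit of transcripts corrected for length, for 24520 gene names, scaled by the authors to a sum of 1000000 per library. The tool that made the TPM values is not given in the sources used here.

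The rows that name no gene were left out of library sizes and ratios. Gene rows held 77.1% of counted reads in the parental library, 76.8% in YFP-negative, 77.7% in YFP-low, 77.5% in YFP-medium and 75.7% in YFP-high. Reads outside annotated genes made up 9.11% to 11.0%, reads without a unique alignment 7.64% to 7.77%, ambiguous reads 4.06% to 4.33%, unaligned reads 0.809% to 0.997%, and reads of low alignment quality 0.386% to 0.48%. Gene reads numbered 74.1 M in the parental library, 76.5 M in YFP-negative, 75.9 M in YFP-low, 72.4 M in YFP-medium and 70.7 M in YFP-high. A count of 3 reads, used as the floor per library for genes without reads, equals 0.0361 CPM in YFP-negative and 0.0471 CPM in YFP-high.

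Counts were scaled with the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3, with factors from 0.901 in YFP-high to 1.09 in YFP-negative, and expressed as counts per 1000000 reads (CPM). Genes with at least 1 CPM in at least 1 library were analysed, which left 15099 genes. Log2 ratios used a pseudocount of 0.5 CPM, so they understate the change of low genes. Folds were computed without the pseudocount and carry exact 95% intervals (Clopper-Pearson on both counts given their total). A gene was called higher or lower when its log2 ratio passed 2-fold and its counting interval excluded no change. With 1 library per group there is no spread between samples, so no test was made and no p-value is given. Intervals and floors cover counting error only, not the spread between samples. Reads copied by PCR are not independent molecules, so the intervals may be too narrow for counting error as well. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

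The comparisons were YFP-low, YFP-medium and YFP-high against YFP-negative, YFP-high against YFP-low, and YFP-negative against parental. For 35 gene lists the median log2 ratio of the analysed members was set against medians of 10000 random lists of the same size, matched on mean expression in 20 bins and drawn with replacement. A list is called above or below random lists past the 97.5th or 2.5th percentile. The percentile describes these libraries. Genes called in YFP-high were parted by the share of their log2 ratio already reached at lower YFP. Early genes reached at least 0.5 of it in YFP-low, intermediate genes reached that share in YFP-medium only, and late genes in neither. Ordered genes rose or fell at every step from YFP-negative to YFP-high.

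The lists, the size rule, the response classes, the alternatives and the rule for named genes were fixed before the data were examined. Named genes are E2F1 and ESR1, the 10 higher and 10 lower called genes of each comparison whose interval bound lies farthest from no change, up to 4 members of each list with the largest change in YFP-high and at least 5 CPM in 1 of both libraries, and 5 genes per response class and direction. Genes named outside this rule are said to have been chosen after their values were seen. Alternatives were DESeq2 1.42.0 size factors, total counts, no filter, a filter of 5 CPM, a pseudocount of 2 CPM, the deposited TPM with the size rule alone, a 1.5-fold rule, the parental library as baseline, and a share of 0.67 for the classes. A correction for transcript GC content, with values for 12760 of the 15099 genes (84.5%), and the leaving out of genes of 3 regions with more than 1 placement were chosen after seeing the data.

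The size rule was checked on simulated libraries with 200 changed genes among 15099 and an assumed biological coefficient of variation of 0.1. In the simulated YFP-high against YFP-negative comparison it recovered 93.5% of 3-fold and 98.5% of 4-fold changes, called 2.5% of 1.5-fold changes, and called 0 unchanged genes. In the simulated YFP-low against YFP-negative comparison it recovered 89.5% of 3-fold and 95.0% of 4-fold changes. A spread of 0.1 hardly allows 2-fold differences, so the 0 does not measure false calls in the real libraries. There YFP-negative and parental cells differed in 763 genes. The reference annotation at hand is of another genome build, so no coordinates are given.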

Results

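The study asked how the level of E2F1, a transcription factor that drives entry into S phase and can also drive apoptosis, relates to cell fate. Gene reads were counted in 5 U2OS libraries: parental cells, and the YFP-negative, YFP-low, YFP-medium and YFP-high fractions of cells carrying a doxycycline-inducible, OHT-activated YFP-E2F1 fusion. Depth lay between 70.7 M and 76.5 M gene reads per library. Each group held 1 library, so no difference given here has a replicate check.

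E2F1 transcripts followed the YFP gates. The level was 85.6 CPM in parental cells, 106 CPM in YFP-negative, 163 CPM in YFP-low, 362 CPM in YFP-medium and 998 CPM in YFP-high. Against YFP-negative, E2F1 was 1.53-fold higher in YFP-low (counting interval 1.49 to 1.58), 3.41-fold higher in YFP-medium (3.32 to 3.49) and 9.40-fold higher in YFP-high (9.19 to 9.61). YFP-negative cells held 1.24-fold more E2F1 than parental cells. Gene counts do not separate the construct from the cell's own E2F1. ESR1, the oestrogen receptor alpha gene, had 15 reads in parental, 3 in YFP-negative, 3 in YFP-low, 16 in YFP-medium and 25 in YFP-high. The last equals 0.392 CPM, against 998 CPM for E2F1, so ESR1 reads do not measure the level of the construct.

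**Figure D1:**
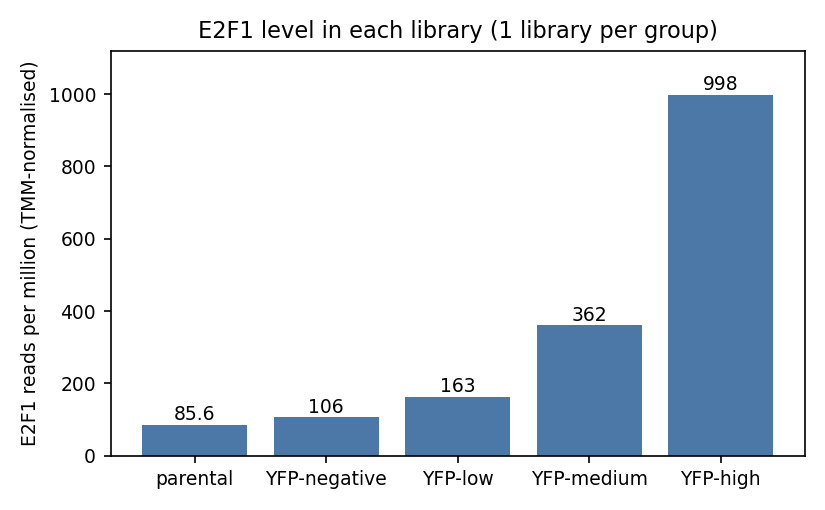
E2F1 level in TMM-normalised CPM (vertical axis, linear from 0) in each of the 5 libraries, 1 bar per library. The bars climb from 85.6 CPM in parental cells to 998 CPM in the YFP-high fraction.

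The comparison of YFP-low with YFP-negative asked what a small increase of the construct does. FOXJ1, a forkhead factor of ciliated cells, was 7.20-fold higher (6.08 to 8.56), and C2orf72 was 5.19-fold higher (4.70 to 5.74). ABCG2, a drug efflux transporter, went from 32.9 to 130 CPM. In all, 313 genes were higher and 9 lower, and with the parental library as baseline 900 and 665. These 322 called genes (2.13%) were fewer than the 763 (5.05%) called between YFP-negative and parental cells. The 9 lower genes included HTR2A, a serotonin receptor, at 2.66-fold (2.11 to 3.38), and BST2, an interferon-induced membrane protein, at 2.45-fold (1.98 to 3.04). The others included AJ420595, ASAH2, C6orf48, Metazoa_SRP, WDR46 and DNM3OS; reads of Metazoa_SRP, a repeated RNA family, and of C6orf48 and WDR46, in the MHC region, are uncertain. Without genes of the pseudoautosomal, MHC and 17q21 regions 6 lower genes were left.

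Among the genes farthest from no change in YFP-low were several that did not follow YFP. SLC25A6, a mitochondrial ADP/ATP carrier gene of the pseudoautosomal region, had 40.1 CPM in YFP-low, 0.865 CPM in YFP-negative, 0.695 CPM in YFP-medium and 0.33 CPM in YFP-high. ABHD16A had 135 reads in YFP-low, 4 in YFP-negative, 10 in YFP-medium and 4 in YFP-high. ASMTL had 4.31 CPM in YFP-low, 0.349 CPM in YFP-negative, 4.51 CPM in YFP-medium and 0.455 CPM in YFP-high. CSF2RA and NSFP1 had 1.94 and 1.23 CPM in YFP-low and 0.816 and 0.848 CPM in YFP-high. GNL1, an MHC region gene, was higher in all 3 YFP-positive fractions but had 1.44 CPM in parental cells against 0.12 CPM in YFP-negative. LOC113230 and LHFPL3, a tetraspan family member, were instead higher at each YFP step, with log2 ratios of 2.44 and 1.21 in YFP-low.

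In YFP-low 7 of the 34 lists with analysed genes lay above random lists and 7 below. E2F targets of G1/S and replication had a median log2 ratio of 0.24, with 5 of 53 genes higher and 0 lower. CCNE2 and CCNE1, the E-type cyclins, had log2 ratios of 1.57 and 1.46. Mitosis genes had a median of 0.50 with 0 of 37 past the size rule. Cyclin-dependent kinase inhibitors had 3 of 7 genes higher, CDKN2C at 1.55, CDKN1B at 1.41 and CDKN2D at 1.10. MYC-linked ribosome biogenesis genes had a median of -0.16 and p53 targets of -0.11. With the parental library as baseline these 2 medians turned to 0.21 and 0.26. The G1/S median then turned to -0.03, below random lists. In YFP-negative against parental cells the G1/S median was -0.23.

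The comparison of YFP-medium with YFP-negative covered a further increase of the construct. FOXJ1 was 30.4-fold higher (25.9 to 35.9), FA2H, a fatty acid hydroxylase, 20.6-fold (17.6 to 24.2), SLC16A6, a monocarboxylate transporter family member, 16.8-fold, and the transcription factor MYB 16.7-fold (14.8 to 18.8). GRIK3, DRD5, NXPH3, C2orf72, LOC113230 and PPP2R3B were the other genes at the top; PPP2R3B is a pseudoautosomal gene with 10 reads in parental cells, 1 in YFP-negative, 87 in YFP-medium and 55 in YFP-high. On the lower side LIF, a cytokine of the IL-6 family, was 4.00-fold lower (3.79 to 4.22) and HTR2A 6.39-fold (4.51 to 9.31). TNFAIP6, FAM13C, CXCR7 and the pseudoautosomal gene PLCXD1 were also lower. In all, 1472 genes were higher and 339 lower, and total-count scaling gave 1084 and 784.

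By list, G1/S targets had a median of 0.47 in YFP-medium with 10 of 53 genes higher (0.26 against the parental library, within random lists), and kinase inhibitors 1.63 with 4 of 7 higher. Targets of p53 had a median of -0.37 with 2 of 32 higher and 0 lower, and of 0.07 against the parental library. YAP and TGF-beta response genes had a median of -0.64 with 6 of 15 lower, and NF-kB genes -0.56 with 3 of 19 lower; against the parental library the NF-kB median was 0.67, with 7 higher and 1 lower. WNT and NOTCH genes had 7 of 17 higher and 1 lower, with a median of 0.36.

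The comparison of YFP-high with YFP-negative spanned the full range of the construct. The genes farthest from no change on the higher side had few or no reads in YFP-negative. LHX3, a LIM homeobox factor, had 899 reads against 1, a ratio of 1174 (210 to 46423). GDF10, a TGF-beta family ligand, had 939 reads against 2, a ratio of 613 (169 to 5070). NTSR1, the neurotensin receptor, was 147-fold higher (81.7 to 295) and FGF4, a fibroblast growth factor, 129-fold (71.6 to 259). SLC5A8, FEZF2 and LBX1 had 0 reads in YFP-negative. Set against the floor of 3 reads per library they were 103-fold, 97.9-fold and 92.7-fold higher, with lower interval limits of 82.9, 79.0 and 74.8. DRD5, SHISA7 and KIAA1653 completed this group.

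On the lower side, LIF was 11.8-fold lower in YFP-high (10.8 to 12.9), and CTGF, a secreted matrix protein induced by YAP and TGF-beta, was 7.31-fold lower (7.11 to 7.51), from 672 to 91.9 CPM. HTR2A was 36.1-fold lower (16.4 to 99.2), G0S2, a lipolysis inhibitor, 22.8-fold (8.67 to 85.0) and MAML2, a NOTCH coactivator, 8.62-fold (7.02 to 10.7). LOC150197, LOC339535, GALNTL2, SNORD77 and LINC00173 were also among the lower genes. In all, 3065 genes were higher and 1710 lower, so 64.2% of the called genes were higher. With total counts the split was 2415 higher and 2865 lower, or 45.7% higher. Relative to TMM, total-count scaling moved the median log2 ratio of all genes by -0.26 in this comparison, -0.20 in YFP-medium and -0.17 in YFP-high against YFP-low. The deposited TPM moved it by -0.12 in YFP-high and -0.10 in YFP-medium.

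**Figure D2:**
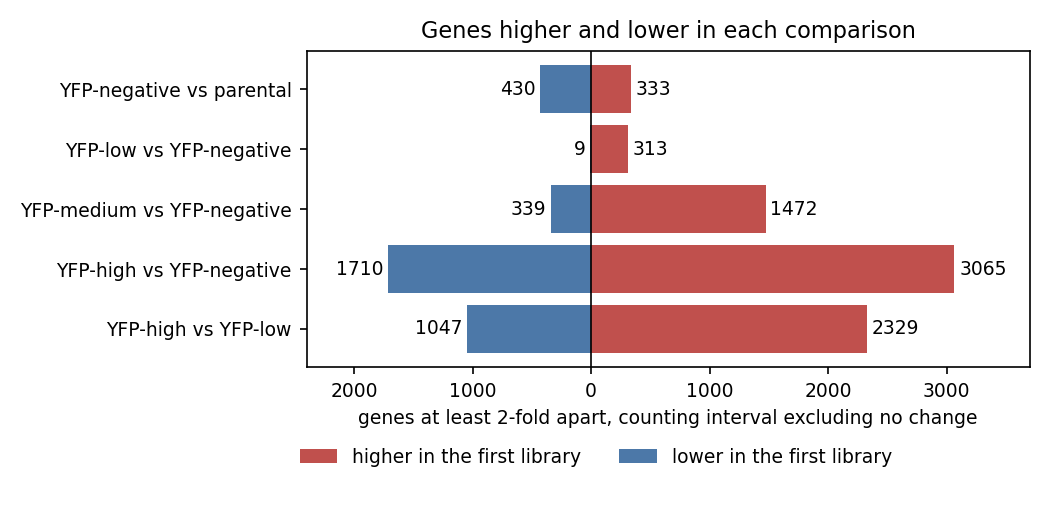
Number of genes at least 2-fold higher (right, red) or lower (left, blue) in the first library of each of the 5 comparisons, with 1 library per group and TMM scaling. YFP-high against YFP-negative gave 3065 higher and 1710 lower genes, YFP-low against YFP-negative 313 and 9.

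Of 53 E2F targets of G1/S and replication, 8 were higher, 2 lower and 43 neither in YFP-high, with a median of 0.43 above random lists. Against the parental library the median was 0.40, close to the upper limit of 0.41 of random lists but within it, with 10 higher and 4 lower. The genes named next are given against YFP-negative. CCNE2 was 5.68-fold higher, CDC25A, a phosphatase that activates CDK2, 5.32-fold (5.17 to 5.47), CCNE1 4.59-fold (4.50 to 4.68) and DSCC1, a cohesion factor, 3.96-fold (3.85 to 4.07). The lower members, named after their values were seen, were ORC1 and MCM5, both parts of the replication licensing machinery, with log2 ratios of -1.57 and -1.35. In the E2F and pocket protein family 3 of 15 genes were higher and 0 lower, E2F2 at 5.33-fold, LIN54 at 4.49-fold and E2F8 at 2.94-fold, and the median was 0.70 (0.45 against the parental library, within random lists).

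The median of mitosis genes was highest below the highest YFP level. This median log2 ratio was 0.50 in YFP-low, 0.66 in YFP-medium and 0.25 in YFP-high, the last turning to -0.02 with total counts. Of the 37 genes 30 had their highest level in YFP-medium, 7 in YFP-low and 0 in YFP-high. The drop was small for each gene: 0 of the 37 passed the size rule between YFP-high and YFP-medium. PRC1, a spindle midzone protein, and MKI67, a proliferation marker, were higher in YFP-high, at 2.41-fold and 2.16-fold. Replication-dependent histone genes had medians of 0.37, 0.69 and 0.69 in the 3 fractions, and 3 of 12 were higher in YFP-high. Of these genes 10 had their highest level in YFP-medium.

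Cyclin-dependent kinase inhibitors, which restrain the cell cycle, had a median of 1.83, with 4 of 7 genes higher and 0 lower. CDKN1C was 28.9-fold higher (25.5 to 32.8), with log2 ratios of 0.28, 1.89 and 4.65 from YFP-low to YFP-high. CDKN2C was 7.99-fold (7.76 to 8.23), CDKN2D 3.65-fold higher (3.43 to 3.88), and CDKN1B had a log2 ratio of 2.57.

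Of 33 pro-apoptotic genes 11 were higher, 2 lower and 20 neither in YFP-high. MAP3K5, the kinase ASK1, was 10.5-fold higher (9.98 to 11.0), HRK 10.7-fold (8.60 to 13.4), APAF1, the scaffold of the apoptosome, 7.67-fold (7.39 to 7.96) and BCL2L11, the BH3-only protein BIM, 7.49-fold (7.17 to 7.83). The lower members, named after their values were seen, were the initiator caspases CASP8 and CASP9, at -1.99 and -1.23. The list's median of 0.20 lay within random lists and turned to -0.05 with total counts. Against the parental library it was 0.30, also within random lists, with 12 genes higher, 6 lower and 15 neither. Of 13 anti-apoptotic genes 2 were higher and 4 lower, with a median of -0.59. Against the parental library the median was 0.08, with 4 higher and 1 lower. BCL2 was 5.72-fold higher (5.51 to 5.93), TRAF1 4.59-fold lower (4.03 to 5.24), BIRC3 3.60-fold lower (3.27 to 3.97) and BCL2L1 3.00-fold lower (2.91 to 3.09). Against the parental library BIRC3 and TRAF1 had log2 ratios of 0.08 and 0.61.

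Targets of p53 had a median of -0.51, below random lists, with 4 of 32 genes higher and 8 lower. Against the parental library it was -0.29, within random lists. PPM1D, a phosphatase that acts against p53, was 5.12-fold higher, POLH, a translesion polymerase, 2.97-fold and BBC3, the BH3-only protein PUMA, 2.89-fold, whereas the exonuclease AEN was 2.96-fold lower. Of 32 DNA damage and repair genes 1 was higher, FANCA at 2.89-fold, and 2 lower, the kinase ATR at 2.45-fold and RAD50 at 2.02-fold; EME1 had a log2 ratio of -0.87. The median was -0.23.

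YAP and TGF-beta response genes had a median of -1.18, with 9 of 15 genes lower and 1 higher. INHBA, an activin subunit, was 7.05-fold lower (6.46 to 7.71) and PMEPA1 5.89-fold (5.64 to 6.16). Extracellular matrix and adhesion genes had a median of -0.39 with 9 of 30 genes lower and 0 higher, CYR61 at 4.59-fold and the integrin ITGA2 at 3.89-fold among them.

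MYC was 2.71-fold lower (2.61 to 2.82). MYC-linked ribosome biogenesis genes had a median of -0.84, with 10 of 27 genes lower and 1 higher, and against the parental library of -0.61 with 5 lower and 3 higher. RRS1 was 4.81-fold, NOP16 4.00-fold, POLR1B, an RNA polymerase I subunit, 3.35-fold and RRP12 2.76-fold lower. Ribosomal protein genes had a median of -0.25 with 0 of 37 past the size rule; RPL13, RPL37, RPS18 and RPL23 had log2 ratios of -0.61, -0.59, -0.53 and -0.52. Cholesterol synthesis genes had a median of -0.60 with 7 of 26 genes lower and 1 higher. MSMO1 was 2.47-fold and HMGCS1 2.39-fold lower, and INSIG1 2.35-fold higher.

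WNT and NOTCH genes had a median of 1.57, with 10 of 17 genes higher and 1 lower. DLL1, a NOTCH ligand, was 41.6-fold higher (29.9 to 59.7), HEY1, a NOTCH target, 35.5-fold (33.5 to 37.6), the ligand JAG2 18.8-fold (17.2 to 20.4) and the WNT target AXIN2 11.4-fold (10.6 to 12.2). PI3K signalling and growth factor receptor genes had a median of 0.53, with 12 of 27 genes higher and 1 lower. FGFR3 was 36.7-fold (33.2 to 40.6), FGFR2 8.39-fold, FOXO1 8.06-fold and PDGFRA 7.37-fold higher. Polycomb and DNA methylation genes had a median of 0.80 with 5 of 21 genes higher and 0 lower, SUZ12 at 3.16-fold, EZH2 at 2.73-fold, RBBP7 at 2.63-fold and JARID2 at 2.62-fold.

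In YFP-high 6 of the 34 lists with analysed genes lay above random lists and 7 below. The comparison of YFP-negative with parental cells also gave 6 above and 7 below, so these counts are not particular to YFP-high. For YFP-high against the parental library 5 lay below and 3 or 5 above, since lists close to the limit changed side between both draws of the random lists. Mitochondrially encoded genes had 0 analysed members.

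**Figure D3:**
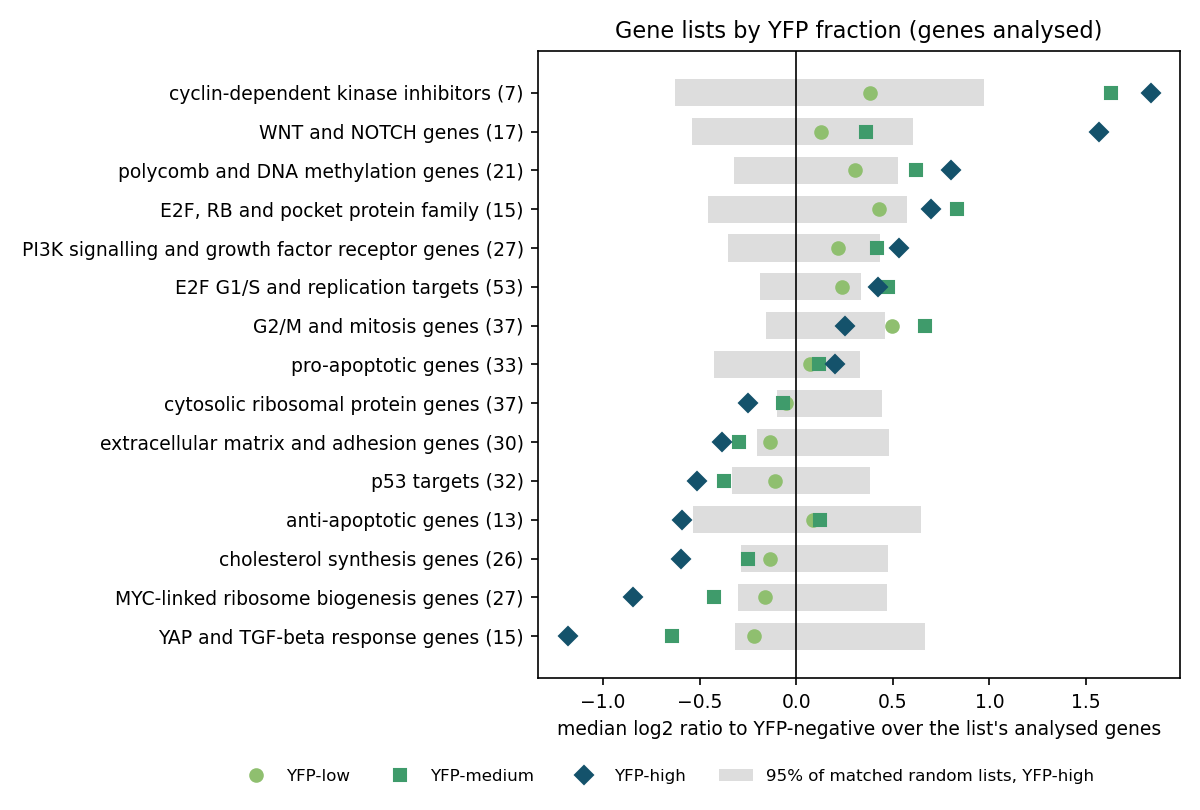
Median log2 ratio to YFP-negative (horizontal axis) of the 13 lists outside random lists in YFP-high and of the mitosis and pro-apoptotic lists, with the number of genes in parentheses. Markers are the YFP-low, YFP-medium and YFP-high libraries and grey bars hold 95% of matched random lists in YFP-high; the YFP-high medians run from -1.18 for YAP and TGF-beta response genes to 1.83 for cyclin-dependent kinase inhibitors, and with total counts the mitosis and pro-apoptotic medians in YFP-high turned to -0.02 and -0.05.

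The remaining lists had no median outside random lists in YFP-high. Inflammatory NF-kB genes had 3 of 19 genes higher and 7 lower (median -0.41), CCL2 at 6.87-fold lower, CXCL3 at 7.96-fold higher; CCL20 had a log2 ratio of -2.09, and of 0.01 against the parental library. Interferon-stimulated genes had 1 of 17 higher and 6 lower (-0.49). USP18 was 17.3-fold higher, whereas DDX58 and STAT2 were 2.99-fold and 2.49-fold lower, and OAS3 had a log2 ratio of 0.99. Immediate early genes had 4 of 22 higher and 4 lower (0.32), EGR2 at 6.53-fold and EGR1 at 3.35-fold higher and KLF6 at 4.85-fold lower. Hypoxia genes had 7 of 16 higher and 2 lower (0.33), NDRG1 at 5.07-fold, KDM3A at 4.43-fold and EGLN1 at 3.57-fold higher, and the glucose transporter SLC2A3 at 4.44-fold lower.

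Autophagy and lysosome genes had 4 of 25 higher and 1 lower (median -0.12), led by TFEB, a regulator of lysosome genes, at 7.79-fold and the kinase ULK2 at 4.35-fold. ATF4 and integrated stress response genes had 2 of 27 higher and 3 lower (-0.07), with NUPR1 at 2.44-fold and AARS at 2.31-fold lower. Unfolded protein response chaperones had 2 of 16 higher and 1 lower (-0.10), CRELD2 at 3.01-fold and DNAJB9 at 2.57-fold higher and EDEM1 at 2.23-fold lower. Of 12 heat shock genes 1 was higher (-0.20), HSP90AA1 at 2.17-fold. Glycolysis genes had 3 of 22 higher and 2 lower, ENO2 at 3.74-fold higher and PFKM at 2.52-fold lower; their median of -0.02 turned to 0.03 with DESeq2 size factors. Nuclear-encoded oxidative phosphorylation genes had 0 of 32 past the size rule (-0.20), with COX5A at 0.74 on the log2 scale.

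Oestrogen receptor targets, listed because OHT binds the receptor part of the construct, had 3 of 12 genes higher and 2 lower (median -0.42). MYB was 42.0-fold higher (37.4 to 47.3) and NRIP1 2.36-fold, whereas RARA was 3.07-fold lower. Osteoblast markers had 2 of 9 higher (0.29), BMP2 at 12.9-fold (12.1 to 13.8) and MSX2 at 4.83-fold. Markers of other cell types gave 1 of 8 higher for epithelial genes (-0.45), EPCAM at 3.52-fold, and 1 of 6 higher and 1 lower for endothelial genes (-0.07), ROBO4 at 2.67-fold lower. Leukocyte markers had 1 of 4 higher, CORO1A at 3.70-fold, with a median of 0.17 that turned to -0.04 with total counts. Neuronal markers had 1 of 9 higher, with a median of 0.08 that turned to -0.10 with total counts and -0.01 with TPM; NEFL and SYP had log2 ratios of 0.99 and 0.82. Housekeeping genes had 1 of 16 higher (0.28). Against the parental library the YFP-high medians were 0.08 for NF-kB, 0.11 for autophagy, 0.06 for integrated stress response and 0.02 for heat shock genes, 0.01 for oestrogen receptor targets and -0.32 for osteoblast markers.

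The response classes asked at which YFP level the genes called in YFP-high had moved. Early higher genes, 348 of 3065 (11.4%), included ABCG2, with log2 ratios of 1.97, 3.16 and 3.71 from YFP-low to YFP-high, the receptor GPR12 and the kinase SBK1. Intermediate higher genes, 1303 (42.5%), included FA2H at 1.69, 4.06 and 5.59, the potassium channel KCNK10 at 1.46, 3.30 and 5.41, NXPH3 and PREX2. Late higher genes, 1414 (46.1%), included LHX3 at 0.24, 0.40 and 4.83, NTSR1 at 0.40, 0.41 and 4.98, KIAA1653 at 1.04, 2.26 and 4.95, GDF10 and SLC5A8. The pseudocount shrinks low levels most, so the late class of low genes can depend on it. Without it KIAA1653 was 22.3-fold higher in YFP-medium and 169-fold in YFP-high, past the share of 0.5 on the log2 scale. NTSR1, at 2.57-fold and 147-fold, stayed under that share. Lower genes were early in 54 cases (3.16%), intermediate in 872 (51.0%) and late in 784 (45.8%). With a share of 0.67 in place of 0.5, 90 higher genes were early, and the lower genes were 9 early, 269 intermediate and 1432 late. LIF, HTR2A, CTGF and G0S2 were intermediate, and INHBA, MYEOV, MAML2 and RIN2 were late, INHBA at -0.45, -1.29 and -2.75. Early lower genes included the small nucleolar RNAs SNORD77 and SNORD93.

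Members of the lists differed in class. Of the 8 higher G1/S targets 5 were early, 3 intermediate and 0 late, and of the 4 higher kinase inhibitors 3 were early and CDKN1C was late. The 11 higher pro-apoptotic genes were 3 early, 5 intermediate and 3 late. The 10 higher WNT and NOTCH genes were 0 early, 5 intermediate and 5 late, and the 7 higher hypoxia genes 0 early, 1 intermediate and 6 late.

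**Figure D4:**
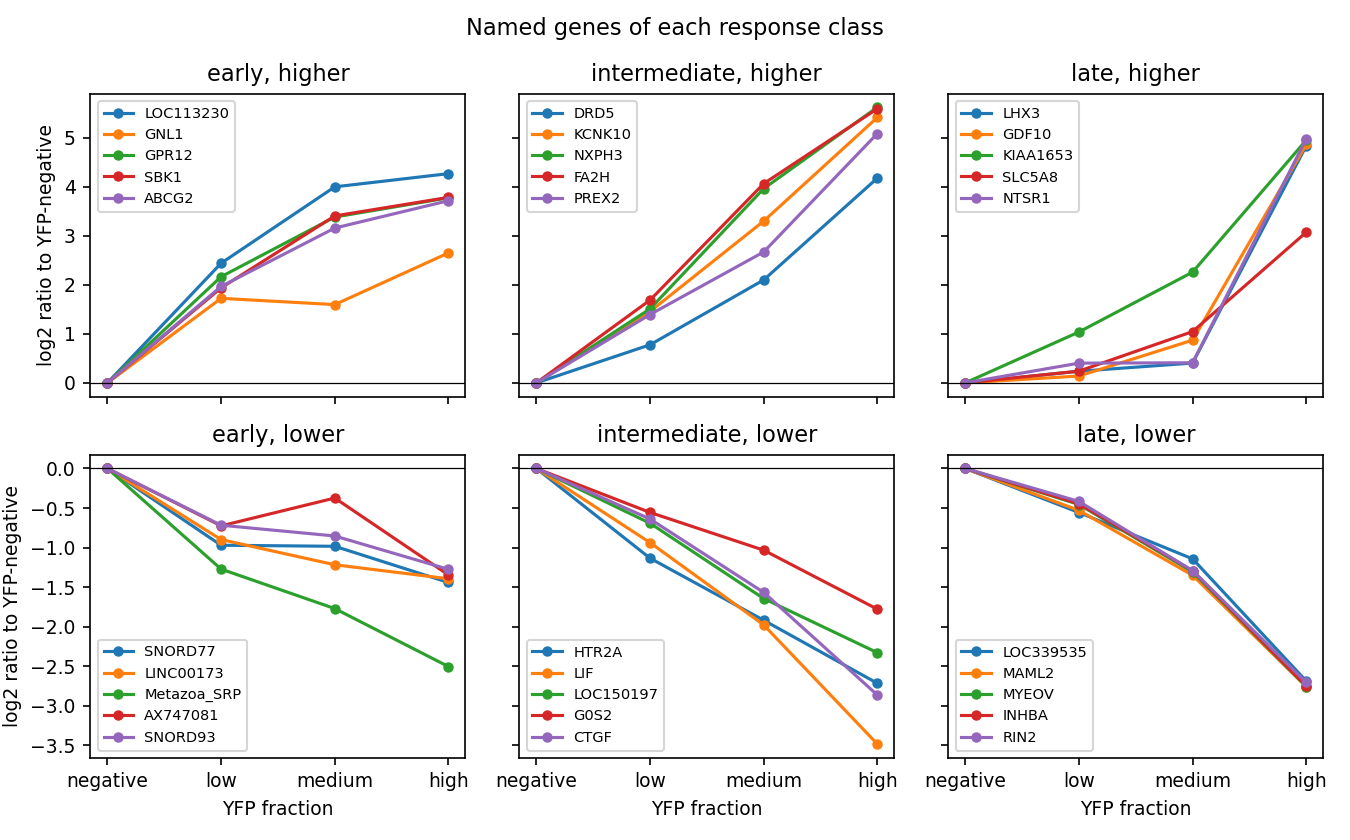
Log2 ratio to YFP-negative (vertical axis) across the 4 YFP fractions (horizontal axis) for the 5 named genes of each response class, higher genes above and lower genes below, 1 library per fraction. The late gene LHX3 is at 0.40 in YFP-medium and 4.83 in YFP-high, and the late gene KIAA1653 at 2.26 and 4.95. All ratios carry the pseudocount of 0.5 CPM, on which the late class of KIAA1653 depends. The early gene ABCG2 is at 1.97 in YFP-low.

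With the parental library as baseline of YFP-low and YFP-medium, 749 higher and 375 lower genes were early. Of the genes higher in YFP-low, 304 of 313 were also higher in YFP-high, against 63.5 for independent lists; for YFP-medium it was 1380 of 1472 against 299. With the parental library as baseline of YFP-low alone, 618 of 900 were shared against 183. Among lower genes 5 of 9 in YFP-low and 285 of 339 in YFP-medium were also lower in YFP-high, and with the parental library as baseline of the former fractions 193 of 665 and 538 of 1234. Simulations with no effect shared 0 genes, but their assumed coefficient of variation of 0.1 leaves no calls to share, so they do not measure what the shared library adds. Part of the excess may come from the shared YFP-negative library. Levels were ordered along all 4 fractions for 7865 genes (52.1%), 3602 rising and 4263 falling. Random order in each gene would give 8.33%. But all genes share the same 4 libraries, and the TMM factors fell at each step, from 1.09 in YFP-negative to 0.901 in YFP-high. Genes are thus not ordered independently, and 8.33% is no test of the 52.1%. Levels were ordered for 3859 (80.8%) of the genes called in YFP-high. These genes were also selected for a difference between the end fractions, so that chance value does not hold for them either.

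The comparison of YFP-high with YFP-low asked what the step between 2 YFP-positive fractions adds. C1QL2, a complement-like synaptic protein, was 152-fold higher (108 to 221), from 0.426 to 64.8 CPM, and GDF10 190-fold (87.1 to 520). WNT2 and its receptor family member FZD10 had 385 and 476 reads against 1 and 2, ratios of 468 (83.5 to 18542) and 289 (79.7 to 2397). MYOD1, a muscle regulator, NPTX1, a neuronal pentraxin, and the muscarinic receptor CHRM2 had 0 reads in YFP-low. Against the floor of 3 reads per library they were 122-fold, 96.1-fold and 88.8-fold higher. Their lower interval limits were 98.96, 77.53 and 71.6. LIF was 6.13-fold lower, HTR2A 13.6-fold (6.02 to 37.9) and G0S2 13.0-fold (4.81 to 49.0). SLC25A6, CRLF2, ABHD16A and ASMTL were lower as well; of these SLC25A6, ABHD16A and ASMTL were also among the higher genes of YFP-low. In all, 2329 genes were higher and 1047 lower, and total counts gave 1932 and 1640.

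By list, YAP and TGF-beta response genes had a median of -1.09 with 8 of 15 genes lower, ribosome biogenesis genes -0.71 with 8 of 27 lower, and WNT and NOTCH genes 1.54 with 11 of 17 higher. Anti-apoptotic genes had a median of -0.58 with 5 of 13 lower and 1 higher, and pro-apoptotic genes 0.20, within random lists, with 8 of 33 higher and 1 lower. Mitosis genes had a median of -0.19 with 0 of 37 past the size rule.

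The comparison of YFP-negative with parental cells gives the difference between 2 libraries without sorted YFP. The labels give the parental cells the same treatment but leave open whether they passed the sorter, which bears on every value against them. IL13RA2, an interleukin 13 decoy receptor, was 71.8-fold higher in YFP-negative (32.7 to 197), SLC16A6 29.5-fold (16.3 to 59.6), and FOXJ1 had 158 reads against 2, a ratio of 75.3 (20.5 to 627). AK131347, ZNF431 and NRK had 0 reads in parental cells and were at least 57.2-fold, 33.4-fold and 26.1-fold higher. WNT11, a WNT ligand, was 52.0-fold lower (34.5 to 82.3), CXCL14, a chemokine, 14.8-fold (13.4 to 16.4), YTHDC1, a reader of methylated RNA, 18.2-fold (13.9 to 24.2) and MN1, a transcriptional regulator, 10.3-fold (9.82 to 10.9), from 196 to 19.0 CPM. In all, 333 genes were higher and 430 lower.

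By list, anti-apoptotic genes had a median of 0.49 with 4 of 13 higher in YFP-negative, NF-kB genes 0.52 with 5 of 19 higher, and ribosome biogenesis genes 0.46 with 0 of 27 past the size rule. Targets of p53 had a median of 0.27 and G1/S targets -0.23, the latter with CCNE1 and CCNE2 higher, from 70.3 to 157 CPM and from 23.3 to 54.1 CPM. Extracellular matrix genes had a median of -0.37, with 1 of 30 higher and 3 lower. HEY1 and BCL2, also higher in YFP-high, had log2 ratios of 2.65 and 2.00; these were named after their values were seen.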

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

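Reads given to no named gene are outside the comparisons. Their classes were set against both libraries with no YFP, and 4 of these 6 classes took a larger share of counted reads in YFP-high than in either. Reads outside annotated genes made up 11.0% in YFP-high, 9.86% in YFP-negative and 9.60% in parental cells. Unaligned reads made up 0.997%, 0.889% and 0.809%, and reads of low alignment quality 0.48%, 0.439% and 0.465%. The class without a gene name held 682 reads in YFP-high (0.00073%), 243 in YFP-negative and 279 in parental cells. No spread between samples is known, and no explanation was tested.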

How the results depend on the processing

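GC correction and leaving out genes of 3 regions with more than 1 placement were tried after seeing the data. No paired analysis was possible because each group has 1 library. Of 180 values of the main comparisons under alternatives, 138 stayed within their limits, 24 were larger and 18 smaller. Of 816 list medians, 736 stayed within their spread, 63 were larger, 11 smaller, and 6 whose spread excluded 0 changed sign. Counted whatever their spread, 77 of the 816 changed sign, 29 of them with the parental library as baseline and 21 with total counts. Of 5263 values of named genes, 4057 stayed within their counting interval, 524 were larger, 675 smaller and 7 changed sign. Without a filter on low counts, and without genes of more than 1 placement, the counts of called genes stayed within 1.5 times. Except where said, the cause was not tested.

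With DESeq2 size factors the log2 ratio of E2F1 in YFP-high was 3.28. With total counts it was 2.96, and lower genes numbered 16 in YFP-low, 784 in YFP-medium, 2865 in YFP-high and 1640 in YFP-high against YFP-low. Total counts also gave 97 early and 1783 intermediate lower genes, and a mitosis median of -0.0185 in YFP-high. The deposited TPM gave 22 lower genes in YFP-low and 3.10 for E2F1. GC correction gave 3.07 for E2F1.

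A filter of 5 CPM, which leaves fewer genes, gave 5 lower genes in YFP-low and 25 early lower genes. A pseudocount of 2 CPM, which shrinks the ratios of low genes, gave 206 higher and 1 lower in YFP-low. Lower genes were 140 in YFP-medium, 1078 in YFP-high and 585 in YFP-high against YFP-low. YFP-negative against parental gave 165 higher and 245 lower, and the lower classes held 15 early and 475 late genes.

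The 1.5-fold rule, wider by construction, gave 1080 higher and 218 lower genes in YFP-low, 2849 and 1806 in YFP-medium, and 3854 lower genes in YFP-high. YFP-high against YFP-low gave 3820 higher and 3137 lower, and YFP-negative against parental 1047 and 1323. A share of 0.67, stricter by construction, gave 90 early higher genes, and 9 early, 269 intermediate and 1432 late lower genes.

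With the parental library as baseline, YFP-low had 900 higher and 665 lower genes, YFP-medium 1234 lower, and E2F1 in YFP-high a log2 ratio of 3.54. Early genes were 749 higher and 375 lower, and intermediate lower genes 521. In YFP-low the medians turned to -0.0268 for G1/S targets, 0.26 for p53 targets, 0.0426 for oxidative phosphorylation and 0.21 for ribosome biogenesis, and in YFP-medium to 0.0705 for p53 targets. Among medians whose spread included 0, NF-kB genes turned to 0.59 in YFP-low, 0.67 in YFP-medium and 0.0815 in YFP-high, interferon-stimulated genes to 0.20 in YFP-low, and anti-apoptotic genes to 0.0815 in YFP-high. BIRC3 turned to 0.0815 in YFP-high and 0.78 in YFP-medium, CCL20 to 0.0133, ROBO4 to 0.16 and TRAF1 to 0.61 in YFP-high, C6orf48 to 0.25 in YFP-low and GNL1 to -0.0475 in YFP-medium.

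Depth limits low genes: 3 reads equal 0.0361 CPM in YFP-negative, so genes without reads there have only a lower bound.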

Other observations

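Among genes near 0 without YFP, the set that appeared in YFP-high was small. Of 9704 genes under 0.1 CPM in parental and YFP-negative cells, 1 reached 1 CPM in YFP-low, 4 in YFP-medium and 100 in YFP-high. After LHX3 and GDF10 the highest of these, named after their values were seen, were POU4F3, a factor of sensory hair cells, at 9.73 CPM, the dopamine receptor DRD5 at 9.40 CPM and the motor neuron factor MNX1 at 8.88 CPM. GRIK3, a kainate receptor subunit, reached 5.62 CPM and the noradrenaline transporter SLC6A2 5.37 CPM.

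The tests on genes of the 3 regions below were chosen after the result was seen, as was the count that treats genes without a GC value as not higher; the other tests were set before their results were seen.

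Genes near 0 without YFP reached 1 CPM in YFP-high. Genomic DNA or another even background would lift such genes alike. But 91.1% of the 9704 stayed under 0.1 CPM in YFP-high, which argues against it as the cause of rises to 1 CPM. In YFP-low 96.8% stayed under 0.1 CPM. Gene length was not taken into account, so a thinner background in YFP-high is not excluded. A GC content trend as the whole cause would leave under 50% of the 100 genes 2-fold higher once it is removed. Of the 69 genes with a GC value 100% remained so. That is 69% of the 100 (exact interval 59.0% to 77.9%) even if the others did not. But the genes were picked for their rise, and 100% of the 69 were 2-fold higher before the correction. The shift of their median log2 ratio, from 2.37 to 2.30, is the value that bears on the trend. Their median GC content was 57.3%, against 48.5% for analysed genes. The trend was fitted over all genes, so a GC effect particular to such genes is not excluded. The construct's level may account for the pattern, and explanations other than these were not tested.

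Genes of the pseudoautosomal, MHC and 17q21 regions differed between libraries without following YFP, as SLC25A6 did. Of the 58 genes 22.4% were ordered by fraction against 52.1% of all genes, but the regions were picked because genes there were seen not to follow YFP, so this decides nothing about the level of the construct. Reads with several placements could move such genes in any pair of libraries. Their median absolute log2 ratio between YFP-negative and parental cells lay at the 55.6th percentile of random lists. That between YFP-low and YFP-negative, looked at afterwards, lay at the 99.7th. But genes of these regions were among those farthest from no change in YFP-low, and the regions were picked for such genes. The 99.7th percentile thus decides nothing. The 55.6th percentile is of a median over 58 genes and does not exclude an effect on few of them. Both explanations stay open.

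YFP-negative and parental cells differed in genes that also differed between YFP-high and YFP-low, comparisons that share no library. Construct activity in YFP-negative cells would give shared genes of the same direction; the ratio to independent lists was 1.17 for higher genes (60 genes against 51.4, with a counting interval that includes 1) and 1.74 for lower genes, which leaves it open. Genes that vary in any pair of libraries would also be shared in opposite directions, and those ratios were 1.67 (1.38 to 2.02) and 2.99 (2.32 to 3.78), consistent with that explanation. FOXJ1, SLC16A6, FA2H and HEY1 were among the 60 genes higher in both. Whether the 2 cell populations differ for a biological reason was not tested.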
